A study of Arabidopsis thaliana with 28 samples.

How the data were processed

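Shoots of 3-week-old Arabidopsis thaliana plants (Col-0) were grown at 20 °C and 70% humidity in a 12 h light period at 150 µmol per square metre and second and harvested 4 h after the onset of light, per the labels' protocols. Each replicate pooled 14 plants, and 1 µg of total RNA per sample was turned into biotin-labelled cRNA, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 per probe set and array, from 2.89 to 22277. RMA is the only tool in the submitters' processing notes, which state no version, so its steps were not checked. RMA works on the log2 scale, and that the deposited values are its antilog is inferred from their range. The 28 arrays were grouped by the genotype in their labels into 14 groups of 2 biological replicates. Detection calls are not given in the values used here, so no level was called present or absent, and a depth does not apply to arrays. Their number limits the precision.

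The values were put on the log2 scale. Of 22747 probe sets, 1 control probe set was left out and 22746 were tested, without a filter on low values. A model with 1 mean per group was fitted to all 28 arrays with limma 3.58.1 in R 4.3.3, which left 14 residual degrees of freedom, 17.7 with the 3.67 that limma adds from all probe sets. The moderated test of limma was run two-sided for 23 contrasts: 13 lines against wild type, 8 suffixed lines against the unsuffixed line of the same protein, BAM8_Ox against BAM7_Ox, and the interaction of both mutations. The contrasts of bam7 bam8 with bam7 and with bam8 were added after the data were seen. P-values were adjusted by Benjamini-Hochberg within a contrast, and a probe set was called at an adjusted p under 0.05. The 23 contrasts, the test, the threshold, the other settings and the rule for naming probe sets were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

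Per contrast and direction, names were taken from the called probe sets with the largest change whose arrays in one group all lie outside those of the other. Not all of these are printed in the Results, and a printed one is not always the largest. For BAM8-Cat_Ox against BAM8_Ox, the Results give 251727_AT (1.28) but not 264958_AT (1.725). Some left out lost the call often, such as 249895_AT in BAM7-Lig_Ox against BAM7_Ox, in 9 of 13 alternatives. The fixed rule took more names and required that a probe set name 1 gene. No table used here pairs probe sets with genes, so that condition could not be applied and at most 2 probe sets per direction and contrast come from the rule. Array separation was not required for the interaction, which compares 4 groups. Values of 249894_AT, 258124_AT and 250304_AT in other contrasts were chosen after they were seen. For the same reason BAM7 and BAM8 could not be looked up, and the tests of the 29 gene lists, the search for a promoter element and the array quality check from control transcripts were not run.

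The settings fixed beforehand were a fit of only the groups compared (2 residual degrees of freedom, and 4 for the interaction), leaving out the third of probe sets with the lowest mean (15164 remained), a variance trend with robust estimation, the replicate number as a block, cyclic loess normalization of the deposited values, array weights, leaving out 1061 probe sets that end in _s_at or _x_at, and leaving out each array in turn. Chosen after seeing the data were the 25th percentile of each array as a covariate, leaving out the 4 arrays with the lowest 25th percentile, the comparisons that share no array, 1 wild type array for each of 2 comparisons, the standard for a moved correlation, and taking each list again in each setting. A group left with 1 array in these fits is assumed to vary like the other groups. A count was taken as moved when it changed by more than 1.5 times.

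Fold changes of comparisons that share the wild type were correlated across probe sets and set beside 100 simulations of unchanged groups. Both groups were set against the same simulated wild type, with normal noise of the fitted spread, independent between probe sets. For 11 pairs of comparisons with no array in common, the called probe sets of one, 5 or more in a direction, were tested as a list in the other with limma's camera, with a preset correlation of 0.01 and with an estimated correlation. These gave 42 lists, adjusted together, of which 35 passed with the preset and 27 also with the estimated correlation. The report prints 20 of them, as whole families in both directions: the lists of bam7 bam8, those of BAM8_Ox, and those of each suffix from BAM7 to BAM8. The other 22 run in the reverse direction or start from BAM7_Ox, and some reverse lists are given beside the printed ones.

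The fit was tested on simulated data with 200 of 22746 probe sets changed in 1 group. For BAM8_Ox against wild type it recovered 38% of changes of 0.5 on the log2 scale, 94% of changes of 1, 98% of changes of 2 and 100% of changes of 3, with 11 false calls. For bam7 bam8 against wild type it recovered 34%, 88%, 98% and 100%, with 6 false calls, and for BAM7-N_Ox 40%, 90%, 100% and 100%, with 10. These shares hold for about as many changes as were simulated. With fewer changes the adjusted threshold is stricter, so recovery in comparisons with few calls would be lower. At 258124_AT, -0.90 in bam8, which had 1 call, gave a limma adjusted p of 0.0914, and 0.91 in BAM8_Ox gave 0.00703. Groups of 2 arrays are too small for a test of other splits of the samples or of a single outlying array.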

Results

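Transcript levels were measured in shoots of 3-week-old Arabidopsis thaliana plants of accession Col-0, on 1 expression array of 22747 probe sets per sample. BAM7 and BAM8 are nuclear proteins that carry a beta-amylase-like domain beside a DNA-binding domain, and the series addresses the part of the enzyme-like domain in finding DNA sequences and in activating transcription. The 28 arrays fell into 14 groups of 2 biological replicates: wild type, the mutants bam7, bam8 and bam7 bam8, and 10 groups whose labels end in Ox, here called overexpression lines. Of these lines, BAM7_Ox and BAM8_Ox carry no suffix, and the other 8 carry the suffix DNA, Cat, Lig or N, which the labels do not define. Array medians lay between 23.5 and 25.8 intensity units. The 25th percentile of the arrays ranged from 6.78 to 8.37, with the lowest values in BAM8-Lig_Ox replicate 1, bam7 replicate 1, BAM7_Ox replicate 1 and BAM8-DNA_Ox replicate 2. Replicate arrays correlated across probe sets with Pearson r between 0.99 and 0.997, although probe sets are not independent replicates. The lowest r was that of BAM7-Cat_Ox. Its replicates differed by more than 2-fold at 254 probe sets, against 6 to 78 in the other groups. A spread pooled over all groups may thus be too small for BAM7-Cat_Ox. The number of arrays limits the precision, and the median SE of a log2 fold change was 0.139. The files do not pair probe sets with genes, so probe sets are given by their IDs, and the levels of BAM7 and BAM8 could not be read by name as a check of the labels.

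Because each group held 2 arrays, every count given here rests on a spread pooled over the 14 groups. When only the arrays of the groups compared were fitted, the count fell by more than 1.5 times in 21 of the 23 comparisons. Leaving out wild type replicate 2 raised the count by more than 1.5 times in 13 of the 14 comparisons that use the wild type. The balance of higher and lower probe sets turned round or evened out in at least 1 alternative in 19 of the 23 comparisons, all but bam8, BAM7-DNA_Ox and BAM7-N_Ox against wild type and BAM8_Ox against BAM7_Ox. The counts and their balance were therefore uncertain. None of the probe sets named by the fixed rule changed sign in any alternative run. For those chosen with separated arrays, only cyclic loess and the 25th percentile as a covariate could have reversed a sign. The other alternatives keep the fold change, or use part or a weighting of the same separated arrays. The missing reversals are thus largely set by the rule. A call of the named probe sets printed in the Results held in all but at most 3 of its alternatives unless more losses are given beside it. Where at least 1 array on the lower side of a difference lay under its own 25th percentile, the value given is a lower bound, since such a level may be background. This applies to every change of 249780_AT, 245171_AT, 264514_AT and 252606_AT and to 248969_AT in bam7 bam8.

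Few probe sets passed the threshold where BAM7 or BAM8 alone was lost, and more passed where both were lost, an order of counts that depended on single arrays. Probe set 249894_AT was lower than wild type in bam7 and lower still in bam7 bam8. Probe set 258124_AT fell in bam7 bam8, whereas neither single mutant passed the threshold for it. In bam8 the value of 258124_AT was -0.90 (adjusted p 0.0914) and passed in 2 of 9 alternatives, which leave out the fit of only the groups compared. Its interaction was not detected (-1.02, 95% interval -1.48 to -0.56, adjusted p 0.12). In bam8 the only probe set that passed was 249780_AT, which fell by 3.3 on the log2 scale (SE 0.223, adjusted p 4.93e-07). Its level in bam8, 5.01 intensity units, lay below the 10th percentile of both bam8 arrays (5.24 and 5.31), so that this fall is a lower bound. In bam7, 10 probe sets were higher and 3 lower than wild type at an adjusted p under 0.05, against 3165 at an unadjusted p under that level. The bam7 mutant showed a fall of 249894_AT by 2.30 (SE 0.152, adjusted p 3.27e-07) and of 250304_AT by 1.29 (SE 0.175, adjusted p 0.00604). The probe sets with the largest rise in bam7, 261834_AT at 1.08 and 260077_AT at 1.04 (adjusted p 0.0395 for both), each lost the call in 9 of 13 alternatives. The bam8 mutant gave 1 lower and 0 higher probe sets by limma, with 1455 at an unadjusted p under 0.05. In bam7 bam8, 19 probe sets were higher and 22 lower, of which 4 and 10 differed by 2-fold or more, against 2195 at an unadjusted p under 0.05, fewer than in bam7. There 249894_AT fell by 3.66 (12.7-fold, SE 0.152, adjusted p 1.23e-10) and 258124_AT fell by 2.21 (SE 0.154, adjusted p 3.91e-07). The largest rises in bam7 bam8 were those of 248969_AT at 1.62 (SE 0.284, adjusted p 0.0208) and 253423_AT at 1.14 (SE 0.197, adjusted p 0.0203), which lost the call in 6 of 12 and 5 of 13 alternatives. The bam7 count was 21 without wild type replicate 1, 470 without wild type replicate 2 and 111 without bam7 replicate 2, and without wild type replicate 1 it held 3 higher and 18 lower probe sets. The bam8 count was 9 without wild type replicate 1, 146 without wild type replicate 2 and 3 without bam8 replicate 1, and the bam7 bam8 count was 253 without wild type replicate 2, below the 470 of bam7, and 16 without bam7 bam8 replicate 1.

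The interaction of both mutations asks whether losing one gene had another effect where the other gene was lost too. Few probe sets showed such a difference, 5 with a positive and 6 with a negative interaction, against 1855 at an unadjusted p under 0.05. Probe set 249780_AT had an interaction of 3.39 (SE 0.315, adjusted p 8.02e-05), because its fall in bam8 was absent in bam7 bam8, and this value is a lower bound too. The level of 249780_AT was also low in all BAM8 overexpression lines, so a background that they share with bam8 could give this value as well. Probe set 253666_AT gave 1.42 (SE 0.185, adjusted p 0.00409). The largest negative interactions were those of 255510_AT at -1.97 (SE 0.2, adjusted p 0.000161) and 259290_AT at -1.28 (SE 0.201, adjusted p 0.0257), and the latter lost the call in 8 of 17 alternatives. For 249894_AT no interaction was detected (-0.42, 95% interval -0.87 to 0.03, adjusted p 0.647). The count of 11 became 5 without wild type replicate 1, 73 without wild type replicate 2, 4 without bam7 replicate 2, 4 without bam8 replicate 2, 4 without bam7 bam8 replicate 1 and 3 without bam7 bam8 replicate 2.

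The unsuffixed overexpression lines were compared with wild type and with each other to ask what each protein changed when in excess. With all arrays, BAM8_Ox differed from wild type at more probe sets than BAM7_Ox, and most of those were higher. Both statements failed without wild type replicate 2, where BAM8_Ox had 123 higher and 124 lower probe sets and BAM7_Ox had 515 in all. Compared directly, BAM8_Ox and BAM7_Ox differed at 85 probe sets. In BAM8_Ox, 72 probe sets were higher and 30 lower than wild type, of which 30 and 11 differed by 2-fold or more, against 1838 at an unadjusted p under 0.05. Probe set 248997_AT rose by 4.61 (24.5-fold, SE 0.206, adjusted p 2.25e-10) and 245171_AT by 3.08 (SE 0.12, adjusted p 4.72e-11) in BAM8_Ox. The wild type level of 245171_AT, 4.64 units, was below the 10th percentile of both wild type arrays (5.62 and 5.34), and the levels of BAM8-DNA_Ox and BAM8-Lig_Ox were as low. In the same line 249780_AT fell by 3.27 (SE 0.223, adjusted p 1.34e-07), and 257365_X_AT fell by 1.50 (SE 0.3, adjusted p 0.0268), a call lost in 6 of 12 alternatives. In BAM7_Ox, 5 probe sets were higher and 1 lower, against 3111 at an unadjusted p under 0.05. The BAM7_Ox changes included rises of 266914_AT by 3.49 (SE 0.327, adjusted p 8.84e-05) and 245784_AT by 1.29 (SE 0.176, adjusted p 0.00592), and a fall of 247929_AT by -0.79 (SE 0.103, adjusted p 0.00592), the last 2 of which each lost the call in 4 of 13 alternatives. Against BAM7_Ox, BAM8_Ox was higher at 56 and lower at 29 probe sets, with 248997_AT higher by 4.52 (SE 0.206, adjusted p 3.21e-10) and 266914_AT lower, at -3.46 (SE 0.327, adjusted p 1.68e-05). The BAM8_Ox count was 247 without wild type replicate 2, 166 without BAM8_Ox replicate 1 and 58 without BAM8_Ox replicate 2. The BAM7_Ox count was 20 without wild type replicate 1, 515 without wild type replicate 2 and 1 without BAM7_Ox replicate 1, and it was 0 with the 4 arrays of lowest 25th percentile left out, where 266914_AT, at 3.47 (SE 0.466, adjusted p 0.0682), also lost its call, since its change stayed as large but fewer arrays widened the SE. The direct count of 85 was 44 and 56 without replicates 1 and 2 of BAM7_Ox, and 228 and 50 without replicates 1 and 2 of BAM8_Ox.

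**Figure D1:**
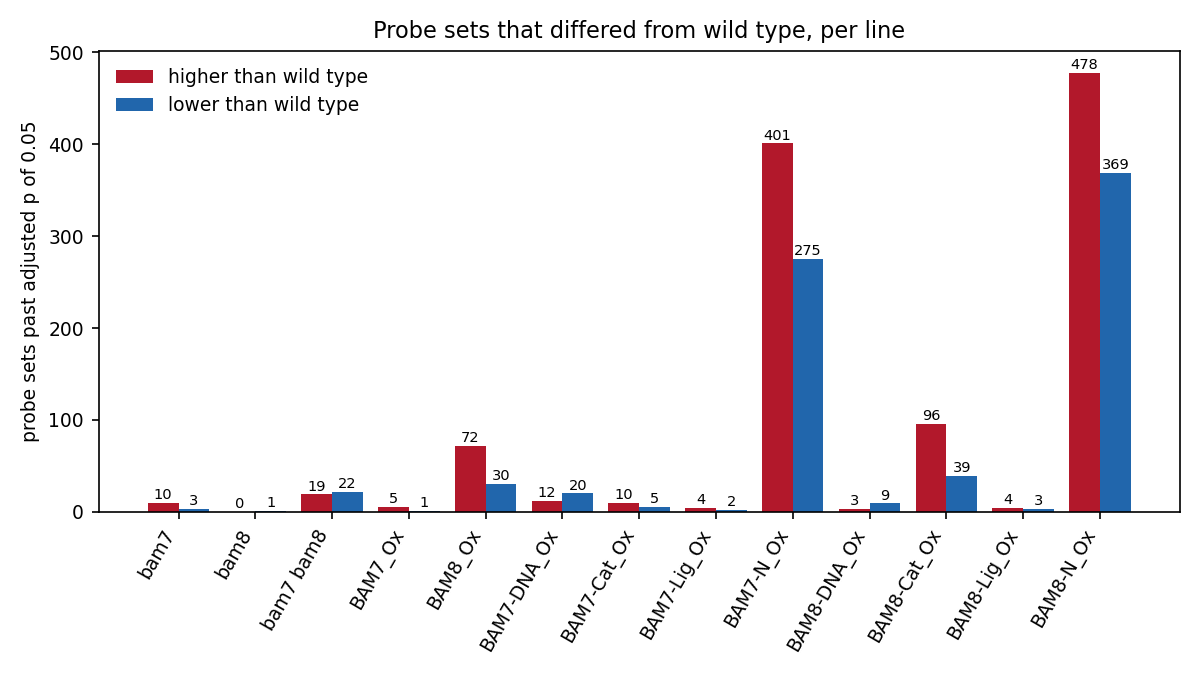
Bars give the number of probe sets that were higher (red) or lower (blue) than wild type at an adjusted p under 0.05, for each of the 13 lines with 2 arrays each. BAM8-N_Ox and BAM7-N_Ox had the highest counts, with 847 and 676 probe sets, and leaving out single arrays moved most counts by more than 1.5 times.

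Probe sets 249894_AT, 258124_AT and 250304_AT were followed through all groups, a choice made after their values were seen. In 9 alternatives for each comparison, none of the calls given here changed sign, and each held in at least 7. These 9 leave out some settings fixed beforehand, among them the fit of only the groups compared. In that limma fit 258124_AT in bam7 bam8 (adjusted p 0.131) and 250304_AT in bam7 (adjusted p 0.449) lost the call. Probe set 249894_AT in bam7 bam8 kept it. All 3 were low where both genes were lost and high in BAM8_Ox, and they fell below the unsuffixed line in both DNA lines and in BAM8-Lig_Ox. Against wild type, 250304_AT was not called in BAM8-DNA_Ox (0.44, limma adjusted p 0.256) or BAM8-Lig_Ox (-0.45, adjusted p 0.244). Nor was 249894_AT in BAM8-DNA_Ox (-0.83, adjusted p 0.0541). The other values of the 3 in these lines were called lower than wild type. At 249894_AT the mean log2 level was 9.17 in wild type, 6.87 in bam7, 8.22 in bam8 and 5.50 in bam7 bam8, and the double mutant was lower than bam7 (-1.37, SE 0.152, adjusted p 0.000186) and lower than bam8 (-2.72, SE 0.152, adjusted p 9.82e-09). The bam8 value of 249894_AT, -0.94 against wild type, did not pass the threshold (adjusted p 0.0588), although it passed in 4 of 9 alternatives. In BAM8_Ox 249894_AT stood at 11.36, a rise of 2.2 (SE 0.152, adjusted p 1.34e-07), and in BAM8-Cat_Ox at 10.97, a rise of 1.80 (SE 0.152, adjusted p 1.66e-06). In BAM7_Ox it was 9.49 and did not differ detectably from wild type (0.32, adjusted p 0.364). Against the unsuffixed line 249894_AT was lower in BAM7-DNA_Ox (-2.64), BAM8-DNA_Ox (-3.03), BAM8-Lig_Ox (-3.61) and BAM8-N_Ox (-2.16), with adjusted p no higher than 1.82e-07. No difference from BAM8_Ox was detected for it in BAM8-Cat_Ox (-0.40, 95% interval -0.72 to -0.08, adjusted p 0.582). Probe set 258124_AT was lower than the unsuffixed line in BAM7-DNA_Ox (-1.83), BAM8-DNA_Ox (-2.74) and BAM8-Lig_Ox (-1.86), and higher than wild type in BAM8_Ox (0.91, SE 0.154, adjusted p 0.00703). Probe set 250304_AT was lower than the unsuffixed line in BAM7-DNA_Ox (-2.40), BAM8-DNA_Ox (-1.32), BAM8-Lig_Ox (-2.21) and BAM8-N_Ox (-1.88).

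**Figure D2:**
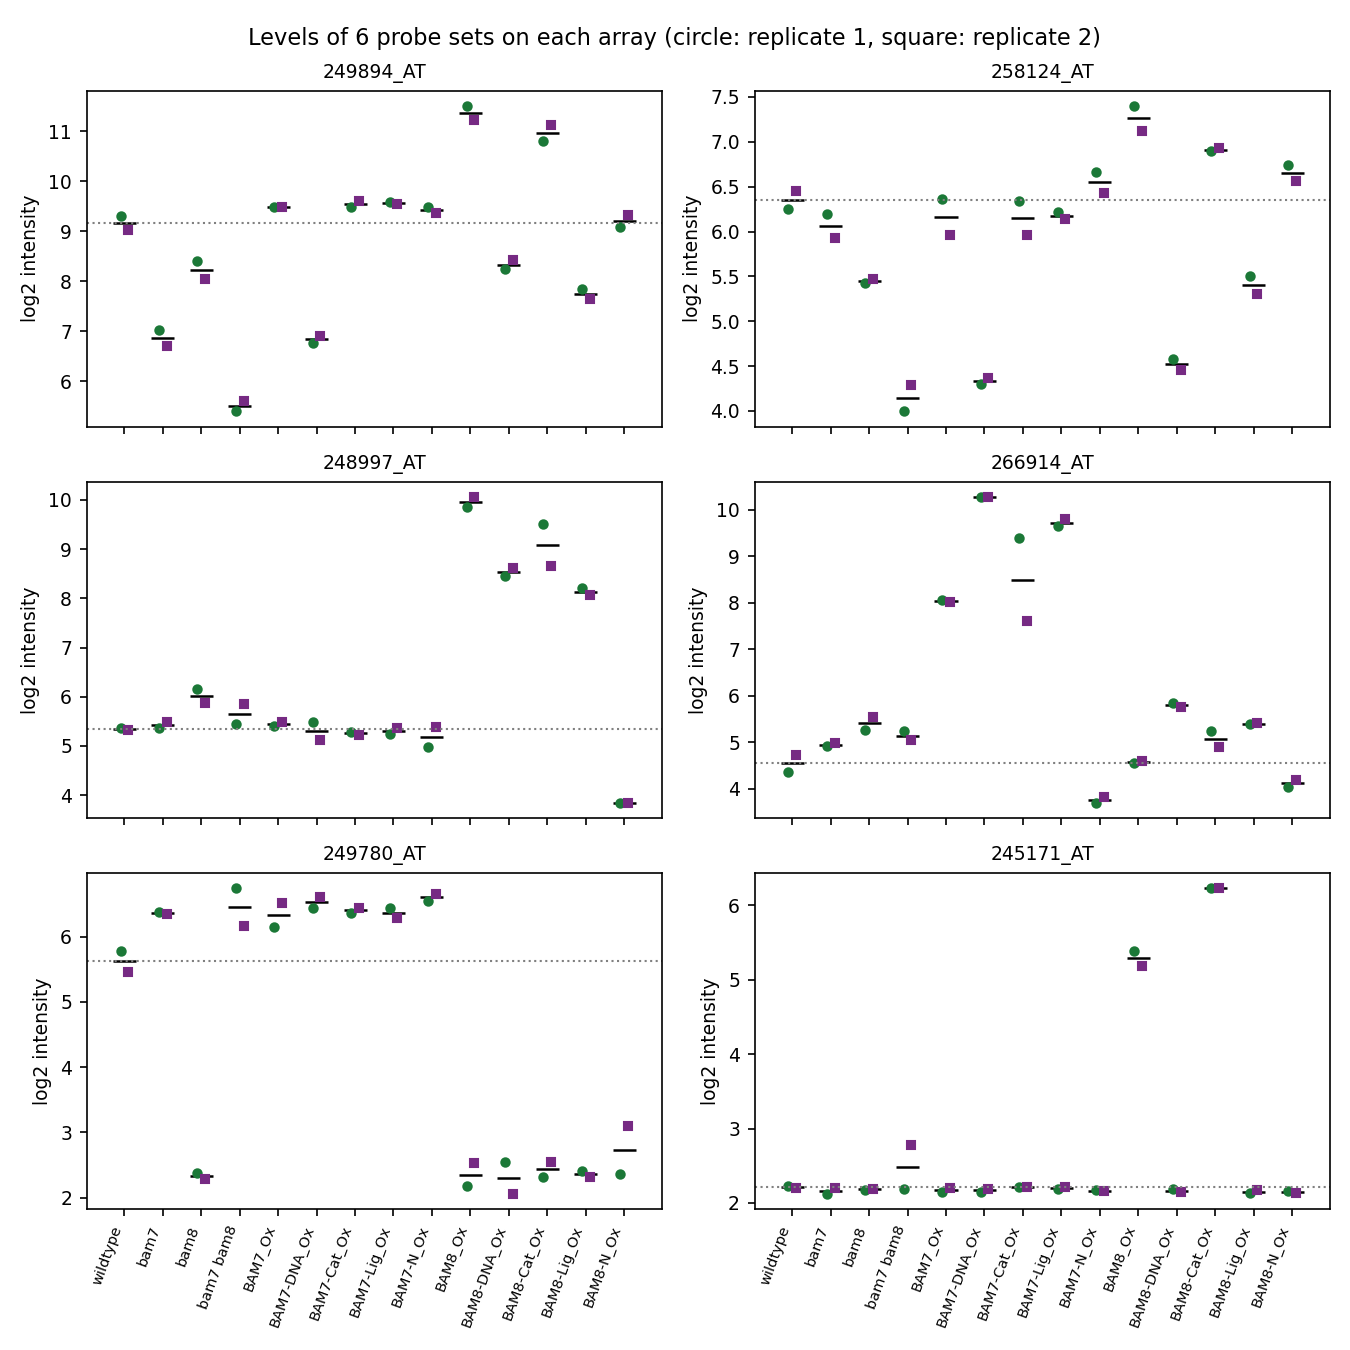
Log2 intensity of 6 probe sets on each array of the 14 groups, with circles for replicate 1, squares for replicate 2, a bar at each mean and a dotted line at the wild type mean. Probe set 249894_AT is lowest in bam7 bam8 (mean 5.50) and highest in BAM8_Ox (mean 11.36).

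The DNA lines were set against wild type and against the unsuffixed line of the same protein. With all arrays, both DNA lines were lower than the unsuffixed line at more probe sets than they were higher. The balance turned round for BAM7-DNA_Ox when only the groups compared were fitted (42 higher, 26 lower) and without its replicate 2 (15 and 14), and for BAM8-DNA_Ox without its replicate 1 (86 and 81). Against wild type, 266914_AT rose in BAM7-DNA_Ox and 248997_AT rose in BAM8-DNA_Ox. BAM7-DNA_Ox was higher than wild type at 12 and lower at 20 probe sets, with a rise of 266914_AT by 5.73 (52.9-fold, SE 0.327, adjusted p 2.9e-08), a rise of 256940_AT by 3.31 (SE 0.259, adjusted p 1.3e-06), and falls of 249894_AT by -2.32 (SE 0.152, adjusted p 1.36e-07) and of 258124_AT by -2.02 (SE 0.154, adjusted p 1.16e-06). BAM8-DNA_Ox was higher than wild type at 3 and lower at 9 probe sets, against 3698 at an unadjusted p under 0.05, with a rise of 248997_AT by 3.19 (SE 0.206, adjusted p 2.23e-07) and falls of 249780_AT by -3.32 (SE 0.223, adjusted p 2.23e-07) and of 245319_AT by -1.86 (SE 0.167, adjusted p 1.15e-05). Compared with BAM7_Ox, BAM7-DNA_Ox was higher at 41 and lower at 60 probe sets, among them 250304_AT at -2.40 (SE 0.175, adjusted p 8.22e-07). Compared with BAM8_Ox, BAM8-DNA_Ox was higher at 54 and lower at 112 probe sets, among them 245171_AT at -3.13 (SE 0.12, adjusted p 3.53e-11), 264514_AT at -3.11 (SE 0.301, adjusted p 1.32e-05) and 256598_AT at 1.50 (SE 0.174, adjusted p 7.77e-05). The BAM7-DNA_Ox count against wild type was 202 without wild type replicate 2, and 15 and 18 without replicates 1 and 2 of BAM7-DNA_Ox, and against BAM7_Ox it was 29 without BAM7-DNA_Ox replicate 2 and 33 and 51 without replicates 1 and 2 of BAM7_Ox. The BAM8-DNA_Ox count against wild type was 22 without wild type replicate 1, 552 without wild type replicate 2 and 102 without BAM8-DNA_Ox replicate 1, where the balance turned to 60 higher and 42 lower. Against BAM8_Ox it was 95 without BAM8-DNA_Ox replicate 2 and 289 without BAM8_Ox replicate 1.

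The Cat lines of both proteins gave different counts. BAM8-Cat_Ox differed from wild type at many probe sets and from BAM8_Ox at few, while BAM7-Cat_Ox gave the reverse order of counts, which did not hold without BAM7_Ox replicate 1, with the 25th percentile as a covariate or with only the groups compared (0 and 0). It nearly vanished without the 4 arrays of lowest 25th percentile (14 against wild type, 15 against BAM7_Ox). Probe set 252606_AT had a mean log2 level of 3.03 in BAM8-Cat_Ox and lay between 7.15 and 7.81 on the 26 other arrays. BAM8-Cat_Ox was higher than wild type at 96 and lower at 39 probe sets, with a rise of 245171_AT by 4.02 (SE 0.12, adjusted p 2.36e-13) and of 264514_AT by 3.93 (SE 0.301, adjusted p 4.6e-07), and falls of 252606_AT by -4.58 (SE 0.12, adjusted p 4.34e-14) and of 249780_AT by -3.19 (SE 0.223, adjusted p 2.13e-07). Against BAM8_Ox, BAM8-Cat_Ox was higher at 18 and lower at 6 probe sets, with 252606_AT at -4.64 (SE 0.12, adjusted p 3.47e-14) and 251727_AT at 1.28 (SE 0.156, adjusted p 0.00209), and 1530 at an unadjusted p under 0.05. BAM7-Cat_Ox was higher than wild type at 10 and lower at 5 probe sets, against 2371 at an unadjusted p under 0.05, with a rise of 266914_AT by 3.95 (SE 0.327, adjusted p 1.26e-05; 3.05 and 4.85 without replicates 1 and 2, whose levels differed) and a fall of 253040_AT by -1.38 (SE 0.199, adjusted p 0.0074). With only the groups compared, the SE of 266914_AT was 0.6 and its call was lost. Against BAM7_Ox, BAM7-Cat_Ox was higher at 127 and lower at 237 probe sets, with 265837_AT at 1.83 (SE 0.321, adjusted p 0.00973) and 259009_AT at -1.83 (SE 0.23, adjusted p 0.00167), which lost the call in 6 and 4 of 13 alternatives. That last count of 364 depended on single arrays: it was 2553 and 233 without replicates 1 and 2 of BAM7-Cat_Ox, 6 and 162 without replicates 1 and 2 of BAM7_Ox, and 13 with the 25th percentile of each array as a covariate, where the count against wild type was 36. The BAM7-Cat_Ox count against wild type was 7 and 139 without replicates 1 and 2 of the wild type, and 1296 and 48 without replicates 1 and 2 of BAM7-Cat_Ox. For BAM8-Cat_Ox the count against wild type was 65 and 298 without replicates 1 and 2 of the wild type and 383 and 73 without replicates 1 and 2 of BAM8-Cat_Ox, and against BAM8_Ox it was 240 without BAM8-Cat_Ox replicate 1, 88 without BAM8_Ox replicate 1, where the balance turned to 24 higher and 64 lower, and 1, a lower one, without BAM8_Ox replicate 2.

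The Lig lines differed from wild type at few probe sets, and BAM8-Lig_Ox differed from BAM8_Ox at more. Without wild type replicate 2 its count against wild type was the larger, at 485. Probe set 266914_AT rose in BAM7-Lig_Ox and 248997_AT in BAM8-Lig_Ox. BAM7-Lig_Ox was higher than wild type at 4 and lower at 2 probe sets, against 1428 at an unadjusted p under 0.05, with 266914_AT up by 5.18 (SE 0.327, adjusted p 1.55e-07) and 256503_AT at -0.79 (SE 0.11, adjusted p 0.00893). BAM8-Lig_Ox was higher than wild type at 4 and lower at 3, against 3839 at an unadjusted p under 0.05, with 248997_AT up by 2.78 (SE 0.206, adjusted p 1.04e-06), 249780_AT at -3.26 (SE 0.223, adjusted p 5.85e-07) and 249894_AT at -1.42 (SE 0.152, adjusted p 0.000224). Against BAM8_Ox, BAM8-Lig_Ox was higher at 87 and lower at 98 probe sets, with 249894_AT at -3.61 (SE 0.152, adjusted p 7.83e-11), 245171_AT at -3.14 (SE 0.12, adjusted p 3.35e-11) and 256017_AT at 1.77 (SE 0.297, adjusted p 0.00547). Against BAM7_Ox, BAM7-Lig_Ox was higher at 17 and lower at 27 probe sets, with 265837_AT at 1.78 (SE 0.321, adjusted p 0.0295) and 247185_AT at -1.04 (SE 0.166, adjusted p 0.0179), which lost the call in 6 and 5 of 13 alternatives. The BAM7-Lig_Ox count against wild type was 12 and 143 without replicates 1 and 2 of the wild type and 27 without BAM7-Lig_Ox replicate 1, and against BAM7_Ox it was 110 without BAM7-Lig_Ox replicate 1 and 1 and 10 without replicates 1 and 2 of BAM7_Ox. That balance turned to 71 higher and 39 lower without BAM7-Lig_Ox replicate 1, and to 23 and 7 without replicate 2. The BAM8-Lig_Ox count against wild type was 22 and 485 without replicates 1 and 2 of the wild type and 48 and 21 without replicates 1 and 2 of BAM8-Lig_Ox, and against BAM8_Ox it was 95 without BAM8-Lig_Ox replicate 2 and 352 and 103 without replicates 1 and 2 of BAM8_Ox.

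With all arrays in the fit, the N lines had the highest counts against wild type among the 13 lines. When only the groups compared were fitted, BAM8-N_Ox had 3, fewer than BAM8_Ox, BAM7-DNA_Ox, BAM8-Cat_Ox and BAM8-DNA_Ox. Without BAM7-Cat_Ox replicate 1 the BAM7-Cat_Ox count of 1296 was higher. Probe sets 266914_AT in BAM7-N_Ox and 248997_AT in BAM8-N_Ox, high in the other overexpression lines of the same protein, were far below the unsuffixed line. Probe set 257365_X_AT rose strongly in BAM7-N_Ox. BAM7-N_Ox was higher than wild type at 401 and lower at 275 probe sets, of which 99 and 56 differed by 2-fold or more, with 257365_X_AT up by 4.60 (24.3-fold, SE 0.3, adjusted p 5.43e-08), 247882_AT up by 3.89 (SE 0.244, adjusted p 3.49e-08) and 254862_AT at -2.56 (SE 0.252, adjusted p 9.31e-06). BAM8-N_Ox was higher at 478 and lower at 369, of which 77 and 49 differed by 2-fold or more, with 264514_AT up by 3.3 (SE 0.301, adjusted p 5.28e-06), 260560_AT up by 2.33 (SE 0.377, adjusted p 0.00165; 1.64 with the 25th percentile as a covariate), 249780_AT at -2.89 (SE 0.223, adjusted p 5.92e-07) and 256527_AT at -2.08 (SE 0.149, adjusted p 2.08e-07). Against BAM7_Ox, BAM7-N_Ox was higher at 348 and lower at 355 probe sets, with 266914_AT at -4.28 (SE 0.327, adjusted p 4.46e-07). Against BAM8_Ox, BAM8-N_Ox was higher at 221 and lower at 160, with 248997_AT at -6.11 (69.2-fold, SE 0.206, adjusted p 3.51e-12) and 266778_AT at 2.09 (SE 0.163, adjusted p 7.96e-07). The BAM7-N_Ox count against wild type was 320 without wild type replicate 1 and 415 and 270 without replicates 1 and 2 of BAM7-N_Ox, and against BAM7_Ox it was 464 and 306 without replicates 1 and 2 of BAM7-N_Ox and 438 and 374 without replicates 1 and 2 of BAM7_Ox. The BAM8-N_Ox count against wild type was 286 and 1469 without replicates 1 and 2 of the wild type and 250 and 442 without replicates 1 and 2 of BAM8-N_Ox, and against BAM8_Ox it was 182 and 200 without replicates 1 and 2 of BAM8-N_Ox and 213 without BAM8_Ox replicate 2.

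Comparisons with the same wild type arrays were set side by side to see how far the lines moved alike. BAM8-Cat_Ox shared the most called probe sets with BAM8_Ox and had the highest correlation with it, although the covariance was larger for BAM8-N_Ox (0.0319 against 0.0289). In BAM8-Cat_Ox and BAM8_Ox 43 probe sets were higher and 14 lower in both, where 0.304 and 0.0514 would be shared by chance without the common controls. BAM8-N_Ox shared 29 higher and 13 lower probe sets with BAM8_Ox and had 3 in the opposite direction. BAM8_Ox and bam7 bam8 shared 2 higher probe sets, and 4 went in opposite directions. Unchanged groups set against the same simulated wild type gave a correlation of fold changes across probe sets of 0.499 (SD 0.00667), because the controls are shared. The measured correlation was 0.645 for BAM8-Cat_Ox with BAM8_Ox, 0.55 for BAM8-N_Ox, 0.484 for BAM8-DNA_Ox and 0.466 for BAM8-Lig_Ox. With BAM7_Ox it was 0.561 for BAM7-DNA_Ox, 0.488 for BAM7-N_Ox, 0.465 for BAM7-Lig_Ox and 0.201 for BAM7-Cat_Ox. For BAM8_Ox it was 0.508 with BAM7_Ox and 0.335 with bam7 bam8. The covariance exceeded the simulated 0.0124 in all pairs but BAM7-Cat_Ox with BAM7_Ox, where it was 0.0091, and the simulation does not separate a shared response from structure that the replicate spread leaves out. With 1 wild type array for each comparison, taken both ways round, a test added after the other results were seen, the correlation was 0.231 and 0.247 for BAM8-Cat_Ox with BAM8_Ox, 0.145 and 0.334 for BAM8-N_Ox, and 0.258 and 0.0328 for BAM7_Ox with BAM8_Ox. No pair was thus highest both ways, and all 10 pairs lay between -0.218 and 0.334, within the range of -0.381 to 0.434 that the replicate differences of pairs of groups gave.

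Pairs of comparisons with no array in common avoid the shared controls, and they were chosen after the data were seen. The pairs still share arrays with each other: 3 of the 4 readings of the bam7 bam8 lists use the same BAM8_Ox arrays, so that high levels of a list in BAM8_Ox alone would give all 3. The reading in BAM7-DNA_Ox shares BAM7_Ox with the last of them. As a list, the 22 probe sets lower in bam7 bam8 shifted down in both DNA lines and in BAM8-Lig_Ox relative to the unsuffixed line, and up in BAM8_Ox relative to BAM7_Ox. Only some of them passed the threshold there. Across all probe sets the correlation with bam7 bam8 against wild type was 0.177 for BAM7-DNA_Ox, 0.356 for BAM8-DNA_Ox, 0.351 for BAM8-Lig_Ox and -0.22 for BAM8_Ox against BAM7_Ox, all within the -0.381 to 0.434 of the replicate differences. The whole profile gives no evidence beyond such differences. Their median log2 fold change was -0.78 in BAM7-DNA_Ox against BAM7_Ox, with all 22 negative and 18 past the threshold (camera, adjusted p 9.23e-61, with estimated correlation 1.4e-09). It was -0.78 in BAM8-DNA_Ox against BAM8_Ox, with all 22 negative and 12 past the threshold (adjusted p 1.75e-42, with estimated correlation 8.46e-09). In BAM8-Lig_Ox against BAM8_Ox the median was -0.58, with 21 of 22 negative and 10 past the threshold (adjusted p 2.6e-31, with estimated correlation 4.64e-08). In BAM8_Ox against BAM7_Ox the median was 0.30, with 19 of 22 positive and 5 past the threshold (adjusted p 2.26e-15, with estimated correlation 2.78e-06). These medians depended on which probe sets entered the list. Without wild type replicate 2 the list grew to 141 probe sets, 19 of them in the original list, and the medians became 0.011, -0.097, -0.12 and 0.084 in the same order, so that the first changed sign. Without wild type replicate 1 the list held 28 probe sets, 12 of them in the original list, with medians of -0.15, -0.14, -0.12 and 0.12, and without bam7 bam8 replicate 1 the second median was -1.17. The lists were chosen on these samples and are not independent evidence about the mutant.

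**Figure D3:**
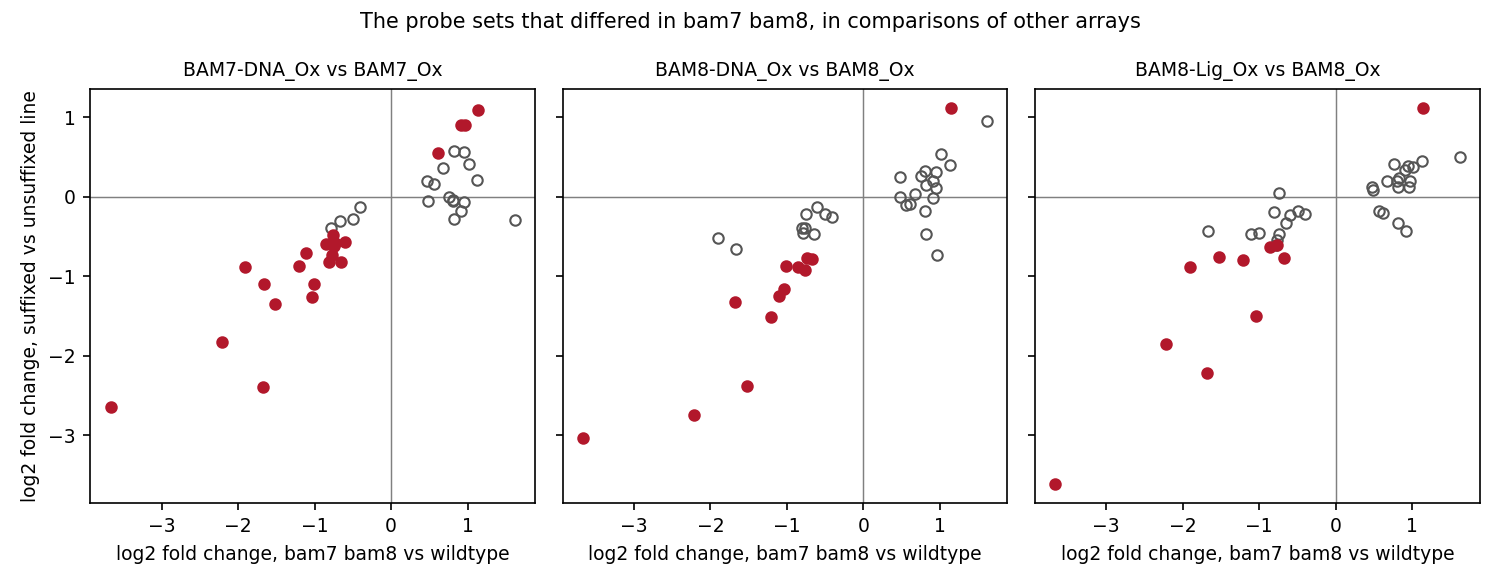
Each point is 1 of the 41 probe sets that differed between bam7 bam8 and wild type, with its log2 fold change there on the x axis and its log2 fold change between a suffixed and the unsuffixed line on the y axis. Filled red points passed the threshold in the comparison on the y axis, 22 in BAM7-DNA_Ox, 13 in BAM8-DNA_Ox and 11 in BAM8-Lig_Ox.

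The 19 probe sets higher in bam7 bam8 had medians smaller in size and larger camera p-values than the lower ones, a difference that was not tested. Their median was 0.20 in BAM7-DNA_Ox against BAM7_Ox, with 11 positive and 4 past the threshold (camera, adjusted p 1.03e-06, with estimated correlation 0.0392). In BAM8-DNA_Ox it was 0.15, with 13 positive (adjusted p 0.00493, with estimated correlation 0.2), and in BAM8-Lig_Ox 0.20, with 15 positive (adjusted p 0.00055, with estimated correlation 0.118). In BAM8_Ox against BAM7_Ox it was -0.022 (adjusted p 0.619, with estimated correlation 0.804). Without wild type replicate 1 the list held 5 probe sets, with medians of 0.56, 0.31, 0.39 and -0.25, and without bam7 bam8 replicate 1 it held 3, too few to test. Without wild type replicate 2 it held 112, with -0.016 in BAM7-DNA_Ox, 0.13 in BAM8-Lig_Ox and -0.11 in BAM8_Ox, and the last then passed (p 3.78e-07). The BAM8-DNA_Ox median was -0.060 without bam7 bam8 replicate 2, 0.23 and 0.13 without replicates 1 and 2 of BAM8-DNA_Ox, where the second no longer passed (p 0.144), and 0.24 and 0.26 without replicates 1 and 2 of BAM8_Ox. The BAM8-Lig_Ox median was 0.31 without BAM8_Ox replicate 2. The BAM8_Ox median was 0.0083 without bam7 bam8 replicate 2 and 0.017 without BAM7_Ox replicate 1.

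Lists of probe sets that changed in BAM8_Ox shifted the other way when BAM8 was lost in addition to BAM7. The lower list did so as well when BAM7 was lost in addition to BAM8, but there it changed sign without either wild type replicate. Whether the shift is tied to BAM8 alone is thus undecided. Across all probe sets the correlation was -0.146 against bam7 and -0.0493 against bam8, within the range of the replicate differences. The 72 probe sets higher in BAM8_Ox than wild type had a median of -0.16 in bam7 bam8 against bam7, with 52 negative and 3 past the threshold (camera, adjusted p 3.6e-12, with estimated correlation 0.00127). Against bam8 the median was -0.019, with 39 negative (adjusted p 0.0034, with estimated correlation 0.108). The 30 lower probe sets had a median of 0.18 against bam7, with 23 positive and 0 past the threshold (adjusted p 1.17e-05, with estimated correlation 0.000953), and of 0.21 against bam8, with 23 positive and 1 past the threshold (adjusted p 1.73e-11, with estimated correlation 1.86e-05). That 1 was 249780_AT, at 4.13 (SE 0.223, limma adjusted p 9.82e-09), whose low levels may be background and which adds to the camera result. The first median was -0.082 without wild type replicate 2, -0.055 without bam7 replicate 1 and -0.001 without BAM8_Ox replicate 1. The median of the lower list against bam7 was 0.032 and 0.049 without replicates 1 and 2 of the wild type and 0.045 and 0.087 without replicates 1 and 2 of BAM8_Ox, and without BAM8_Ox replicate 1 it no longer passed (p 0.0714). Against bam8 the lower list changed sign without wild type replicate 1 (-0.0011) and without wild type replicate 2 (-0.011), and was 0.060 and 0.10 without replicates 1 and 2 of BAM8_Ox. The higher list against bam8 was 0.0073 without bam8 replicate 2, -0.031 without bam8 replicate 1, -0.064 and -0.0024 without replicates 1 and 2 of bam7 bam8, -0.010 without BAM8_Ox replicate 1, where it no longer passed (p 0.23), and -0.064 without BAM8_Ox replicate 2. These lists were likewise taken from the same samples.

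Last, the differences between a suffixed and the unsuffixed BAM7 line were looked up in the BAM8 lines. Mean log2 levels of 266914_AT were 8.03 in BAM7_Ox, 10.27 in BAM7-DNA_Ox, 9.72 in BAM7-Lig_Ox and 8.49 in BAM7-Cat_Ox. Those of 248997_AT were 9.96 in BAM8_Ox, 8.54 in BAM8-DNA_Ox, 8.13 in BAM8-Lig_Ox and 9.08 in BAM8-Cat_Ox. The lists do not separate such differences between lines from the suffix. The lists of the N suffix shifted the same way in both proteins, and so did the lower list of the DNA suffix, although a minority of their members passed the threshold in BAM8. Across all probe sets the correlation between the proteins was 0.275 for N, 0.00924 for DNA, 0.127 for Cat and -0.222 for Lig, each within the -0.381 to 0.434 of the replicate differences. For Cat and Lig no list held under the estimated correlation except the short higher list of Lig. That one reversed with the replicate block (-0.0053), cyclic loess (-0.00095) and the covariate (-0.053). The 348 probe sets higher in BAM7-N_Ox than BAM7_Ox had a median of 0.31 in BAM8-N_Ox against BAM8_Ox, with 286 positive and 77 past the threshold (camera, adjusted p 3.86e-40, with estimated correlation 1.31e-05). The 355 lower ones had a median of -0.13, with 247 negative and 39 past the threshold (adjusted p 4.54e-09, with estimated correlation 0.0253), and -0.21 and -0.054 without replicates 1 and 2 of BAM8-N_Ox. The 60 probe sets lower in BAM7-DNA_Ox had a median of -0.38 in BAM8-DNA_Ox against BAM8_Ox, with 43 negative and 20 past the threshold (adjusted p 1.77e-22, with estimated correlation 3.55e-05), and -0.11 and -1.02 without replicates 1 and 2 of BAM7-DNA_Ox and -0.66 and -0.14 without replicates 1 and 2 of BAM7_Ox. The 41 higher ones had a median of 0.077 (adjusted p 0.000658, with estimated correlation 0.0974), which was -0.065 and -0.039 without replicates 1 and 2 of BAM7-DNA_Ox, 0.20 without BAM8-DNA_Ox replicate 1, 0.22 without BAM7_Ox replicate 2 and 0.17 without BAM8_Ox replicate 1. Read in reverse, the 54 probe sets higher in BAM8-DNA_Ox had a median of 0.185 in BAM7-DNA_Ox against BAM7_Ox. Of these 44 were positive (camera, adjusted p 3.28e-09, with estimated correlation 0.00335).

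For Cat, the 127 probe sets higher and the 237 lower in BAM7-Cat_Ox than in BAM7_Ox had medians of 0.024 and -0.11 in BAM8-Cat_Ox against BAM8_Ox (camera, adjusted p 0.0011 and 7.8e-07, with estimated correlation 0.239 and 0.2). The first median changed sign without BAM7-Cat_Ox replicate 1 (-0.015), BAM7-Cat_Ox replicate 2 (-0.0093), BAM8-Cat_Ox replicate 2 (-0.017) and BAM7_Ox replicate 2 (-0.0003), was 0.036 and 0.011 without replicates 1 and 2 of BAM8_Ox, where the second no longer passed (p 0.128), and had 1 probe set left without BAM7_Ox replicate 1. The second was -0.056 without BAM7-Cat_Ox replicate 1, -0.19 and -0.041 without replicates 1 and 2 of BAM8-Cat_Ox, and -0.057 and -0.063 without replicates 1 and 2 of BAM7_Ox. It no longer passed without BAM8-Cat_Ox replicate 2 (p 0.369) or BAM7_Ox replicate 1 (p 0.297). For Lig, the 17 higher and 27 lower probe sets of BAM7-Lig_Ox had medians of 0.061 and 0.069 in BAM8-Lig_Ox against BAM8_Ox (adjusted p 0.0309 and 0.00524, with estimated correlation 0.0489 and 0.117), so that the lower list went the opposite way. The higher Lig list changed sign without BAM7-Lig_Ox replicate 1 (-0.087), BAM7-Lig_Ox replicate 2 (-0.093), BAM8-Lig_Ox replicate 2 (-0.0079) and BAM8_Ox replicate 2 (-0.046), and was 0.13 without BAM8-Lig_Ox replicate 1 and 0.052 without BAM8_Ox replicate 1, where it no longer passed (p 0.0543 and 0.57). The lower Lig list gave 0.16 without BAM7-Lig_Ox replicate 2, 0.036 without BAM8-Lig_Ox replicate 1, where it no longer passed (p 0.303), 0.17 without BAM8-Lig_Ox replicate 2 and 0.13 without BAM8_Ox replicate 1. Without BAM7_Ox replicate 1 the Lig lists held 0 and 1 probe sets, and without BAM7_Ox replicate 2 the higher one held 4, too few to test.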

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

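The covariate test and the test of lost BAM8 function were chosen only after the data were seen, although the bound for the covariate test was written before its value was. The interaction of both mutations passed at 11 probe sets, where the effect of losing one gene differed with the other gene. Besides 249780_AT, the named ones were 253666_AT (1.42), 255510_AT (-1.97) and 259290_AT (-1.28), and no explanation of these was tested. The control probe set that was left out of the tests read 4.7 intensity units in BAM8_Ox replicate 1, above the wild type maximum of 3.61, although on the log2 scale it lay near the floor in all arrays, between 1.66 and 2.23.

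Probe set 249780_AT had an interaction of 3.39, a lower bound because its low levels may be background, since it was low in bam8 and in the 5 BAM8 overexpression groups but at the wild type level or above in bam7 bam8. The fall in BAM8_Ox stayed at -3.18 (SE 0.223) with the 25th percentile as a covariate. The log2 25th percentiles of all arrays lay between 2.76 and 3.07, so the covariate could hardly have removed a fall of that size. These percentiles show no shift of the whole array as large as the fall, but the covariate test itself decides nothing more. The test of lost BAM8 function cannot decide, since bam7 bam8 lying 4.13 (SE 0.223) above bam8 is part of the pattern itself. It shows only that 249780_AT was not low where BAM7 was lost too, and an effect of lost BAM8 that needs BAM7 stays open. Such an effect would not by itself explain mean log2 levels of 2.30 to 2.73 in the BAM8 overexpression groups, near the 2.32 in bam8. A background that the bam8 and BAM8 overexpression lines share may still be the source: 0 other probe sets separated these 6 groups from the other 8, where 100 random choices of 6 groups gave a median of 0 and at most 1. The bound written beforehand, no more than the random median, was met and would count against a shared background, but it was set aside after the value was seen because the random median is itself 0 and a difference at 1 locus needs no other probe set.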

How the results depend on the processing

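Chosen only after the data were seen were the covariate, the exclusion of 4 arrays, the use of 1 wild type array per comparison, the standard for a moved correlation and all tests of lists; the other alternatives were planned. None of the named probe sets changed direction: over all alternatives 963 values kept direction and call, 183 kept direction only and 0 reversed. Where probe sets were chosen for separated arrays, only cyclic loess and the covariate could have reversed them, so this is largely set by the rule. Leaving out probe sets ending in _s_at or _x_at moved none of the 23 counts by more than 1.5 times, and leaving out dim probe sets moved 3. Counts below are for a line against wild type unless a second line is named, and the cause of a change was not tested unless fewer arrays, probe sets or degrees of freedom explain it. Arrays give no depth, and signal over background was examined only by the filter on dim probe sets and by setting low levels beside the percentiles of their arrays. The planned tests of 29 gene lists and of a promoter element were not run. Replicate numbers showed no pairing common to all groups: replicate differences of 91 pairs of groups correlated between -0.381 and 0.434 (median 0.012), above 0.1 in 24. Pairing within some groups is not excluded. The r was 0.434 for bam7 with BAM7_Ox, 0.41 for bam7 with BAM8-Lig_Ox and 0.356 for BAM7_Ox with BAM8-Lig_Ox.

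With only the groups compared, where 2 residual degrees of freedom (4 for the interaction) estimate the spread, the count was 1 for bam7, 0 for bam8, 1 for bam7 bam8, 1 for BAM7_Ox, 4 for BAM8_Ox, 5 for BAM7-DNA_Ox, 0 for BAM7-Cat_Ox, 1 for BAM7-Lig_Ox, 135 for BAM7-N_Ox, 7 for BAM8-DNA_Ox, 6 for BAM8-Cat_Ox, 2 for BAM8-Lig_Ox and 3 for BAM8-N_Ox. In that fit it was 0 for BAM7-Cat_Ox and 0 for BAM7-Lig_Ox against BAM7_Ox, 19 for BAM8-DNA_Ox, 0 for BAM8-Cat_Ox, 14 for BAM8-Lig_Ox and 1 for BAM8-N_Ox against BAM8_Ox, 12 for BAM8_Ox against BAM7_Ox and 0 for the interaction. With dim probe sets left out it was 3 for bam8, 12 for BAM7-Lig_Ox and 21 for BAM8-DNA_Ox. With trend and robust it was 3 for bam8, 14 for BAM7_Ox, 38 for BAM8-DNA_Ox and 12 for BAM8-Lig_Ox. With the replicate block it was 4 for bam7, 23 for BAM7-Cat_Ox, 3 for BAM7-Lig_Ox and 4 for BAM8-Lig_Ox. With array weights it was 2 for bam7, 8 for bam8, 2 for BAM7-Cat_Ox, 71 for BAM8-Cat_Ox, 3 for BAM8-Lig_Ox, 17 for BAM7-Cat_Ox against BAM7_Ox and 752 for BAM8-N_Ox against BAM8_Ox.

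With cyclic loess the count was 7 for bam7 (4 higher, 3 lower), 5 for bam8 (1 higher, 4 lower), 33 for BAM7-Cat_Ox, 11 for BAM7-Lig_Ox, 31 for BAM8-DNA_Ox (14 higher, 17 lower) and 11 for BAM8-Lig_Ox. Cyclic loess also shifted the balance of directions to 4 higher and 2 lower for BAM7_Ox, 68 and 119 for BAM8-Lig_Ox against BAM8_Ox, 181 and 200 for BAM8-N_Ox against BAM8_Ox, and 8 and 4 for the interaction. The balance turned round or evened out, in higher and lower probe sets, with only the groups compared for bam7 (0 and 1), BAM8-Lig_Ox (1 and 1), BAM7-DNA_Ox against BAM7_Ox (42 and 26) and BAM8-N_Ox against BAM8_Ox (0 and 1). It did so with trend and robust for bam7 (8 and 9), BAM8-Lig_Ox (3 and 9) and the interaction (10 and 5), and with the replicate block for bam7 (1 and 3) and BAM8-Lig_Ox (1 and 3). It also did so with array weights for bam7 (0 and 2), bam7 bam8 (26 and 25), BAM7-Lig_Ox (2 and 2), BAM8-Lig_Ox (1 and 2) and the interaction (5 and 5), and with dim probe sets left out for BAM7-Lig_Ox (6 and 6), BAM8-Lig_Ox against BAM8_Ox (96 and 89) and the interaction (7 and 6). Without probe sets ending in _s_at or _x_at the interaction had 6 and 6. With the covariate the balance turned for bam7 (2 and 3), BAM8-Lig_Ox (1 and 3), BAM8-N_Ox (144 and 145), BAM7-Cat_Ox against BAM7_Ox (7 and 6), BAM7-N_Ox against BAM7_Ox (464 and 424) and the interaction (13 and 9), and without the 4 arrays for bam7 bam8 (17 and 14), BAM8-N_Ox (515 and 553), BAM7-N_Ox against BAM7_Ox (243 and 190) and BAM8-Lig_Ox against BAM8_Ox (106 and 58). With 1 array left out the balance turned or evened out without wild type replicate 1 for bam7 (3 and 18), BAM7_Ox (5 and 15), BAM7-Cat_Ox (3 and 4), BAM7-Lig_Ox (2 and 10), BAM8-Lig_Ox (3 and 19) and the interaction (3 and 2). It did so without wild type replicate 2 for bam7 (213 and 257), BAM7_Ox (244 and 271), BAM8_Ox (123 and 124), BAM7-Cat_Ox (69 and 70), BAM7-Lig_Ox (58 and 85), BAM8-Cat_Ox (134 and 164), BAM8-Lig_Ox (187 and 298), BAM8-N_Ox (677 and 792) and the interaction (40 and 33). The same was seen without bam7 replicate 2 for bam7 (54 and 57) and the interaction (2 and 2), without BAM7-Cat_Ox replicate 1 for BAM7-Cat_Ox (481 and 815), without BAM8-DNA_Ox replicate 1 for BAM8-DNA_Ox (60 and 42) and BAM8-DNA_Ox against BAM8_Ox (86 and 81). Turns were also found without BAM8-Lig_Ox replicate 2 for BAM8-Lig_Ox (8 and 13), without BAM7-DNA_Ox replicate 2 for BAM7-DNA_Ox against BAM7_Ox (15 and 14), without BAM7-Lig_Ox replicate 1 for BAM7-Lig_Ox against BAM7_Ox (71 and 39). Further turns came without BAM7-Lig_Ox replicate 2 for BAM7-Lig_Ox against BAM7_Ox (23 and 7), without BAM7-N_Ox replicate 1 for BAM7-N_Ox against BAM7_Ox (264 and 200), without BAM7-N_Ox replicate 2 for BAM7-N_Ox against BAM7_Ox (168 and 138). Others came without BAM7_Ox replicate 1 for BAM7-N_Ox against BAM7_Ox (246 and 192), without BAM8_Ox replicate 1 for BAM8-Cat_Ox against BAM8_Ox (24 and 64) and BAM8-N_Ox against BAM8_Ox (180 and 265), without BAM8_Ox replicate 2 for BAM8-Cat_Ox against BAM8_Ox (0 and 1) and BAM8-N_Ox against BAM8_Ox (91 and 122). The remaining ones came without BAM8-Lig_Ox replicate 1 for BAM8-Lig_Ox against BAM8_Ox (102 and 58), without bam7 replicate 1 for the interaction (7 and 3), without bam8 replicate 2 for the interaction (3 and 1), without bam7 bam8 replicate 1 for the interaction (2 and 2), and without bam7 bam8 replicate 2 for the interaction (2 and 1). With the 25th percentile as covariate the count was 5 for bam7, 2 for bam8, 24 for bam7 bam8, 1 for BAM7_Ox, 36 for BAM7-Cat_Ox, 17 for BAM7-Lig_Ox, 4 for BAM8-Lig_Ox, 289 for BAM8-N_Ox, 13 for BAM7-Cat_Ox and 23 for BAM7-Lig_Ox against BAM7_Ox, 40 for BAM8-Cat_Ox against BAM8_Ox and 22 for the interaction. With the 4 arrays of lowest 25th percentile left out it was 7 for bam7, 2 for bam8, 0 for BAM7_Ox, 43 for BAM8-Lig_Ox, 30 for BAM7-DNA_Ox, 15 for BAM7-Cat_Ox, 5 for BAM7-Lig_Ox and 433 for BAM7-N_Ox against BAM7_Ox, 90 for BAM8-DNA_Ox against BAM8_Ox, 33 for BAM8_Ox against BAM7_Ox and 5 for the interaction.

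Leaving out 1 array gave counts of 9 to 470 for bam7, 1 to 146 for bam8, 16 to 253 for bam7 bam8, 1 to 515 for BAM7_Ox, 58 to 247 for BAM8_Ox, 15 to 202 for BAM7-DNA_Ox, 7 to 1296 for BAM7-Cat_Ox, 4 to 143 for BAM7-Lig_Ox, 270 to 991 for BAM7-N_Ox, 9 to 552 for BAM8-DNA_Ox, 65 to 383 for BAM8-Cat_Ox, 21 to 485 for BAM8-Lig_Ox and 250 to 1469 for BAM8-N_Ox. Against BAM7_Ox the range was 29 to 75 for BAM7-DNA_Ox, 6 to 2553 for BAM7-Cat_Ox, 1 to 110 for BAM7-Lig_Ox, 306 to 464 for BAM7-N_Ox and 44 to 228 for BAM8_Ox. Against BAM8_Ox it was 95 to 289 for BAM8-DNA_Ox, 1 to 240 for BAM8-Cat_Ox, 95 to 352 for BAM8-Lig_Ox and 182 to 445 for BAM8-N_Ox, and for the interaction 3 to 73.

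Correlations of fold changes moved by more than the simulated SD with dim probe sets left out and with cyclic loess, in that order, to 0.285 and 0.307 for BAM8_Ox with bam7 bam8, 0.493 and 0.494 for BAM8_Ox with BAM7_Ox, 0.502 and 0.506 for BAM7-DNA_Ox, 0.238 and 0.265 for BAM7-Cat_Ox, 0.446 and 0.453 for BAM7-Lig_Ox, 0.436 and 0.438 for BAM7-N_Ox, 0.469 and 0.467 for BAM8-DNA_Ox, 0.452 and 0.45 for BAM8-Lig_Ox, and 0.543 and 0.536 for BAM8-N_Ox, each with its unsuffixed line. For BAM8-Cat_Ox with BAM8_Ox only cyclic loess moved it, to 0.638, and the replicate block moved none of the 10. The simulated SD takes probe sets as independent and is therefore narrow, so passing it does not show a change beyond array-wide noise. With 1 wild type array for each comparison the shared controls fall away and all moved, to 0.0338 and -0.0619 (replicate 1 or 2 for the line named first) for BAM8_Ox with bam7 bam8, 0.258 and 0.0328 for BAM8_Ox with BAM7_Ox, 0.259 and 0.0991 for BAM7-DNA_Ox, 0.0583 and -0.218 for BAM7-Cat_Ox, 0.184 and -0.0467 for BAM7-Lig_Ox, 0.239 and 0.159 for BAM7-N_Ox, 0.0314 and 0.254 for BAM8-DNA_Ox, 0.231 and 0.247 for BAM8-Cat_Ox, 0.0234 and 0.222 for BAM8-Lig_Ox and 0.145 and 0.334 for BAM8-N_Ox.

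Of the 42 lists, 31 kept direction and call with the covariate, 30 without the 4 arrays, 34 with cyclic loess, 34 with estimated correlation, 33 with dim probe sets left out and 40 with the replicate block, as did 261 of 336 values with 1 array left out, where 34 reversed, 15 lost and 10 gained the call and 16 had no value. A suffix list is taken from BAM7 and read in BAM8 unless said otherwise. With estimated correlation the call was lost at medians of -0.019 for the BAM8_Ox higher list in bam7 bam8 against bam8, 0.15 and 0.20 for the bam7 bam8 higher list in BAM8-DNA_Ox and BAM8-Lig_Ox, 0.077 for DNA higher, 0.024 for Cat higher, -0.11 for Cat lower, 0.069 for Lig lower and, from BAM8 to BAM7, 0.13 for Cat higher. With the replicate block Lig higher reversed to -0.0053, and Cat higher, from BAM8 to BAM7, lost the call at 0.10. With cyclic loess the bam7 bam8 higher list reversed to 0.0036 in BAM8_Ox against BAM7_Ox, Lig higher to -0.00095, and, read from BAM8 to BAM7, Cat lower to 0.072 and Lig higher to -0.0021, and Lig lower lost the call at 0.032. With the covariate the call was lost at 0.17 for the bam7 bam8 higher list in BAM8-Lig_Ox, 0.055 for Cat higher, -0.074 for Cat lower and, from BAM8 to BAM7, 0.037 for Cat higher, while Lig higher reversed to -0.053, the higher list of bam7 bam8 against bam8 in BAM8_Ox to -0.0054, and, from BAM8 to BAM7, Cat lower to 0.063 and Lig higher to -0.0027. Without the 4 arrays the call was lost at -0.0071 for the BAM8_Ox higher list in bam7 bam8 against bam8 and 0.14 for the bam7 bam8 higher list in BAM8-DNA_Ox. There the bam7 bam8 higher list in BAM8_Ox against BAM7_Ox reversed to 0.0015, DNA higher to -0.14, the lower list of bam7 bam8 against bam7 in BAM8_Ox to -0.022, and the higher lists of BAM8-DNA_Ox and BAM8-Lig_Ox in bam7 bam8 to -0.027 and -0.020. With dim probe sets left out the call was lost at 0.11 for the bam7 bam8 higher list in BAM8-DNA_Ox, 0.097 for DNA higher, 0.052 for Lig higher, 0.084 for Lig lower and -0.094 for the BAM7_Ox higher list in bam7 bam8 against bam8, and, from BAM8 to BAM7, Cat lower reversed to 0.025 and Lig higher to -0.011.

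With 1 array left out, medians of the bam7 bam8 lower list ran from -0.88 to 0.011 in BAM7-DNA_Ox, and those of the higher list from -0.060 to 0.31 in BAM8-DNA_Ox, -0.016 to 0.56 in BAM7-DNA_Ox and -0.25 to 0.017 in BAM8_Ox against BAM7_Ox. Those of the BAM8_Ox lower list ran from 0.032 to 0.20 in bam7 bam8 against bam7 and -0.011 to 0.26 against bam8, and of its higher list from -0.064 to 0.0073 against bam8. The suffix lists ran from -0.065 to 0.22 for DNA higher, -0.017 to 0.036 for Cat higher, -0.19 to -0.041 for Cat lower, -0.093 to 0.13 for Lig higher and 0.036 to 0.17 for Lig lower, and, from BAM8 to BAM7, -0.20 to 0.12 for Cat lower and -0.062 to 0.064 for Lig higher. Among the other lists, ranges that crossed 0 were -0.028 to 0.43 for the lower list of bam7 bam8 against bam7 in BAM8_Ox, -0.030 to 0.064 and -0.23 to 0.014 for the higher list of bam7 bam8 against bam8 in BAM8_Ox and BAM7_Ox, -0.16 to 0.058 for the BAM7_Ox higher list in bam7 bam8 against bam8, -0.021 to 0.20 for the BAM8-DNA_Ox higher list and -0.025 to 0.14 for the lower list of BAM8_Ox against BAM7_Ox, both in bam7 bam8.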

Other observations

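All tests in this part were chosen only after the results were seen. By the size of the gap to all other arrays, 257365_X_AT in BAM7-N_Ox stood highest above them and 252606_AT in BAM8-Cat_Ox lowest below them. Probe set 257365_X_AT had a mean log2 level of 10.56 there (SD 0.257, n = 2) and 4.33 to 7.68 on the 26 other arrays, and 252606_AT 3.03 (SD 0.146, n = 2) against 7.15 to 7.81 on the others. Between 28 arrays, a gap of more than 1 on the log2 scale to all other arrays was found for 6 higher and 2 lower probe sets in BAM7-N_Ox and for 1 or 0 in each direction in every other group.

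Probe set 248997_AT was high in all BAM8 overexpression groups except BAM8-N_Ox, and 266914_AT in all BAM7 overexpression groups except BAM7-N_Ox. All 16 arrays lay above the 20 others for their probe set. A mislabelled array stays open even so, because the probe sets were picked for this pattern, an exchange among lines of one protein would leave it unchanged, and only 2 of these 8 groups have a probe set that sets both arrays apart by more than 1. Whether each probe set reads the transcript of the overexpressed gene, outside the part that the N lines carry, stays open too. In the N lines mean log2 levels lay below wild type, 3.85 for 248997_AT in BAM8-N_Ox and 3.75 for 266914_AT in BAM7-N_Ox. Neither of the 2 probe sets was lower than wild type in the mutant of the same protein. Mean log2 levels were 6.02 in bam8 against 5.35 for 248997_AT, and 4.94 in bam7 against 4.54 for 266914_AT. Of all probe sets each separated its 8 arrays best (rank 1 for both), with gaps of 1.9 and 1.75 where the next best had -0.009 and -0.041, but this restates the pattern, no table used here pairs the probe sets with genes, and the labels do not define the N suffix.

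Replicate arrays of several groups differed along one common direction, which held 22.5% of the variance of the replicate differences. Across the 14 groups, the position along it correlated with the difference of the log2 25th percentile with Pearson r of -0.967 and Spearman rho of -0.96 (two-sided permutation tests, p 1e-05 for both, the smallest that 100000 permutations can give). The r was -0.945 without BAM8-DNA_Ox and wild type, the groups whose difference of the 25th percentile lay farthest from the median, and the sign of the direction is arbitrary. Both measures were computed from the same array values, so part of the correlation is built in, which the permutation tests do not allow for. The pattern is consistent with a difference in the whole distribution of values between arrays, which may come from the sample or from the array, and no biological explanation was tested.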
